A study of Mus musculus with 8 samples.

How the data were processed

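Mouse lung RNA was measured on 8 one-colour (Cy3) Agilent miRNA arrays (4 vehicle control, 4 Printex 90). Per the labels' protocols, total RNA enriched for small RNA was isolated with a miRvana kit and labelled with Agilent's complete miRNA labelling and hybridisation kit. Per the file headers, the spot intensity values came from Agilent Feature Extraction 10.7.3.1 on grid design 021828, with the background subtracted within each array and no normalization between arrays. The same deposited files give flags per spot (well above background, outlier, saturated) and a total gene signal per miRNA. The authors' deposited value table holds log2 values whose processing is not given in the sources used here. They were matched by recomputing the median over a miRNA's spots of the log2 median spot signal after quantile normalization, without background subtraction, with a correlation of 1 on every array, and the column medians were 5.41 to 5.43. The table was used only as an alternative. Steps before scanning other than those named are not given in the sources used here.

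Groups and replicate numbers came from the sample labels. The processed spot intensity was used, control spots and outlier-flagged spots (2.25% to 2.78% of spots per array) were left out, and no spot was saturated. Spots of a probe were averaged and the probes of a miRNA were summed (1857 probes, 650 miRNAs). A miRNA counted as detected on an array when at least 50% of the kept spots of at least 1 probe were well above background. Each array was divided by its 75th percentile over the 240 mouse miRNAs detected on all 8 arrays. That percentile ran from 580.8 to 804.7 intensity units before scaling, with 248 to 283 mouse miRNAs detected per array. Values were floored at 0.0388, the 5th percentile of the scaled signals of detected miRNAs, and log2 was taken. Fold differences near the floor are understated, and values at the floor have no order. Where a miRNA was detected on no array of a group, the difference is given as a lower bound against the lowest signal of any detected mouse miRNA on each array. The probes of the 47 named miRNAs that were well above background on all arrays did not differ in sign within any of them. miR-135b, miR-21*, miR-122, miR-132, miR-206, miR-214*, miR-872* and miR-129-3p had no such probe, and miR-155, miR-128 and miR-18a had 1. Agreement could not be checked for these. The number of arrays limits the precision.

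The 268 mouse miRNAs detected on at least 4 arrays were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment over all tested. eBayes added 1.02 prior degrees of freedom. Of the tested miRNAs 7 were at the floor on all arrays. 17 lists of miRNAs were matched by exact array name: particle-responsive, inflammation, leukocyte, erythroid, epithelial, multiciliated, endothelial, smooth muscle and mesenchymal, fibrosis, striated muscle, liver, neural, let-7, miR-17-92, Dlk1-Dio3, hypoxia and oxidative stress, and viral. The 16 with at least 3 tested members were tested with camera, at a preset correlation of 0.01 and at an estimated one, and with fry, adjusted over the lists. Counts of members past an adjusted p of 0.05 are given over all tested miRNAs and adjusted over the list alone. Single measures per array were compared with exact permutation tests over all 70 assignments. The groups, tests, lists, rule for named miRNAs and most alternatives were chosen before the data were examined. That rule took all miRNAs past the threshold. As fewer than 10 passed, it added the 5 higher and 5 lower with the smallest p. It also took every detected member of the particle-responsive and inflammation lists, the 2 smallest-p tested members of each other list and the 5 brightest miRNAs. Other members named beside a list were chosen after their values were seen. Names are those of the array design and can be old. The files name no genome build, so no coordinates are given.

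The limma step was tested on simulated values with the spread of the 268 real miRNAs, drawn independently for each miRNA. With 6 changed miRNAs per run it called 77.5% of those changed by 0.5 log2 units, 92.5% at 1 and 97.5% at 2, and 0.305% of the unchanged ones. With 60 changed it called 84.5%, 96.25% and 99.75%, and 1.08% of the unchanged ones. Real miRNAs can move together between arrays, and other groupings of the real arrays gave up to 26 calls. These limma rates therefore need not hold for the real arrays. With the same independent draws and the preset correlation, camera found a list of 7 members shifted by 0.5 in 20 of 20 runs. An unshifted list was called in 1. The real particle-responsive list had an estimated correlation of 0.642 between members, so these runs cannot give its rate of false calls. Alternatives covered the scaling (percentile over all mouse miRNAs, quantile, none), background (normexp with an offset of 50), the detection filter, the summary of probes, the floor, the spread model, array weights, the replicate number as a block, the authors' log2 table, an adjusted p of 0.1 and leaving out each array. The normexp alternative and the uncorrected signal level had been planned on the mean spot signal. They were run on the median spot signal, which the files hold. Slide and scan are the same for all arrays, so neither was a batch. Slide row follows group, so no fit with row as a term could be had. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.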

Results

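Lung microRNA (miRNA) profiles were measured in female C57BL/6 mice that had been pregnant during the exposure. The exposed mice received Printex 90, a commercial carbon black nanoparticle, in water through the trachea, as 4 instillations of 0.067 mg during gestation (days 7 and 10, then days 15 and 18), a cumulative dose of 0.268 mg. The vehicle control mice received water, and lungs were taken 26 to 27 days after exposure, at weaning. The 8 one-colour arrays (4 vehicle control, 4 Printex 90) each carried 13000 spots for 611 mouse and 39 herpesvirus miRNAs. Between 248 and 283 mouse miRNAs were detected per array, 240 of them on all 8 arrays, and 268 were tested. Signals are given relative to each array's 75th percentile, as mean ± SD with n = 4 arrays per group throughout. The labels do not say that each array was a separate mouse, so the p-values measure the spread between these samples. All 8 arrays shared a slide and a scan, but the controls lay in slide row 1 and the Printex 90 samples in row 2, so row and group cannot be told apart.

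The comparison of Printex 90 with vehicle asks which lung miRNAs differed about 4 weeks after repeated particle instillation of the dams. The miRNAs with the smallest p among those higher after Printex 90 were miR-21, its passenger strand miR-21*, miR-146b, miR-135b and miR-148a, and none of the 268 passed an adjusted p of 0.05. miR-21, a miRNA induced in inflamed and injured tissue, measured 18.0 ± 1.79 after Printex 90 against 12.8 ± 0.932 in controls, a 1.40-fold difference (95% interval 1.22 to 1.61). miR-146b, of a family that dampens Toll-like receptor signalling, measured 0.488 ± 0.118 against 0.275 ± 0.0344, a 1.74-fold difference (1.25 to 2.43). miR-135b was not well above background on any control array and was detected on all 4 Printex 90 arrays, at a mean of 0.106 ± 0.0524, at least 4.31-fold higher than the lowest detectable signal of the controls (limma adjusted p = 0.706).

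The log2 differences (Printex 90 minus control) were 0.49 for miR-21 (SE 0.086, limma adjusted p = 0.203, the lowest of all), 0.80 for miR-146b (SE 0.20, limma adjusted p = 0.702), 0.54 for miR-21* (SE 0.16), 1.28 for miR-135b with controls set to the floor (SE 0.42) and 0.20 for miR-148a (SE 0.06). The limma adjusted p was 0.706 for each of the last 3. All 4 Printex 90 arrays lay above all 4 controls for miR-21, miR-146b and miR-21*. miR-21* was detected on 1 control array and on all 4 Printex 90 arrays, and 2 controls lay under the floor, so its difference depends on the floor: it was 0.01 with the floor doubled. Groups that did not overlap, above or below, made up 1.49% of the tested miRNAs on the floored values, where chance gives 2.86%. For miR-135b, Printex 90 replicate 3 lay under the floor with the 4 controls (exact permutation p = 0.143, 2-sided). The smallest p among the lower miRNAs belonged to miR-744 (log2 difference -0.14), miR-872* (-0.24), miR-181b (-0.10), miR-193 (-0.25) and miR-30e* (-0.13), each with a limma adjusted p of 0.706. Of these, miR-744 had all 4 Printex 90 arrays below all controls.

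With limma, 0 miRNAs passed an adjusted p of 0.05, and 15 had an unadjusted p under 0.05 (8 higher, 7 lower), where 13.4 are expected by chance. Of all tested miRNAs 85 were higher and 176 lower, with a median log2 difference of -0.05. That median depended on the processing. Over the alternatives it ran from -0.12 without scaling between arrays to 0.04 with normexp, and it was -0.004 with quantile normalization. The 95% intervals reached a median of 0.19 log2 units to either side, a 1.14-fold change. Without Printex 90 replicate 3, miR-21 and miR-146b both rose (log2 differences 0.63 and 1.06, limma adjusted p = 0.0198 each). That array had the lowest miR-21 and miR-146b of its group (15.5 and 0.323). It also had the lowest 75th percentile signal (580.8), the fewest detected mouse miRNAs (248) and the most flagged spots (2.78%) of all arrays. Over 27 alternatives the limma adjusted p ran from 0.0198 to 0.827 for miR-21 and from 0.0190 to 0.896 for miR-146b. With the mean of the probes' log2 values in place of their sum, miR-135b rose (2.47, limma adjusted p = 0.0252). Over 21 alternatives its log2 difference ran from 0.37 to 2.47 and its limma adjusted p up to 0.846.

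**Figure D1:**
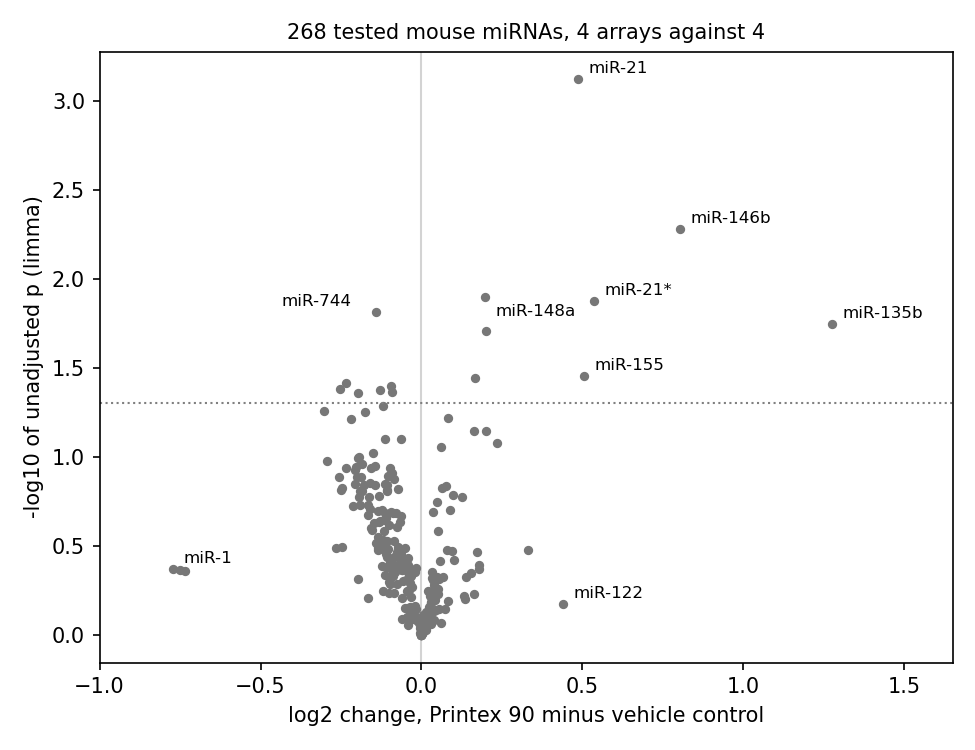
Log2 difference (Printex 90 minus vehicle control) against -log10 of the unadjusted limma p for the 268 tested mouse miRNAs, 1 point each, with the dotted line at an unadjusted p of 0.05. miR-21 stands highest, miR-135b lies farthest to the right at 1.28, and the cluster near -0.75 at low significance holds miR-1, miR-133a and miR-133b.

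The particle-responsive list holds 7 miRNAs chosen from earlier mouse lung studies of instilled or inhaled particles, and 6 of its 7 tested members were higher after Printex 90. Its median log2 difference was 0.49. Over all tested miRNAs 0 members passed, and adjusted over the list alone 3 did: miR-21, miR-146b and miR-135b (limma adjusted p = 0.00529, 0.0183 and 0.0418). For miR-135b all controls were set to the floor and so had no spread, and its exact permutation p was 0.143, 2-sided. It met the detection filter through the Printex 90 arrays only. miR-155, a miRNA of activated macrophages and lymphocytes, measured 0.076 ± 0.0164 against 0.0533 ± 0.0101 and missed that threshold (log2 difference 0.50, adjusted p = 0.0617 with limma over the list alone). miR-449a of multiciliated cells differed by 0.33 (SE 0.32), the liver miRNA miR-122 by 0.44 (SE 0.99) and the muscle miRNA miR-1 by -0.77 (SE 0.91), all within the spread between arrays. The list rose against all other miRNAs in camera with a preset correlation (adjusted p = 1.74e-06), but not with an estimated correlation (adjusted p = 0.335 with an estimated correlation). The mean log2 signal of the list did not differ beyond the spread (exact permutation p = 0.314, 2-sided). fry, which asks whether the members move one way, gave adjusted p = 0.517 for one direction and adjusted p = 0.0834 for either direction. Some of the earlier studies may have used related samples, so the list is not independent evidence of its direction. Without vehicle control replicate 4, 1 member passed over the list alone. Without the 3 miRNAs that the inflammation list also holds, the camera adjusted p was 0.0971.

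Of the inflammation list, miRNAs linked to NF-kB or inflammatory stimuli in either direction, 10 of 14 members were tested. Of these, 7 were higher and 3 lower, with a median log2 difference of 0.12. Adjusted over the list alone, miR-21 and miR-146b rose (limma adjusted p = 0.00756 and 0.0262), and 0 members passed over all tested miRNAs. miR-146a, of the same family as miR-146b, measured 1.41 ± 0.174 against 1.19 ± 0.134 (log2 difference 0.24, limma adjusted p = 0.706). miR-223 of neutrophils and macrophages measured 3.21 on Printex 90 replicate 3 and between 1.70 and 1.93 on the other Printex 90 arrays, against 1.89 ± 0.262 in controls, and its log2 difference of 0.18 (SE 0.21) was 0.05 without that array. It, miR-212 (0.07) and miR-203 (0.02) differed by less than the spread between arrays, as did miR-125a-5p (-0.05), miR-125b-5p (-0.06) and miR-181c (-0.06). miR-132 was detected on 1 array of each group and was not tested. The list rose in camera with the preset correlation (adjusted p = 3.05e-04) and did not with an estimated correlation (adjusted p = 0.107 with an estimated correlation). Its mean log2 signal was -0.58 ± 0.06 after Printex 90 and -0.79 ± 0.06 in controls, all 4 above all 4 (exact permutation p = 0.0286, 2-sided, the smallest that 4 against 4 can give). fry gave adjusted p = 0.366 for one direction and adjusted p = 0.0834 for either direction. The call rests on the 3 members shared with the particle-responsive list, miR-21, miR-146b and miR-155: without them the median was 0.02 and the camera adjusted p 0.374.

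**Figure D2:**
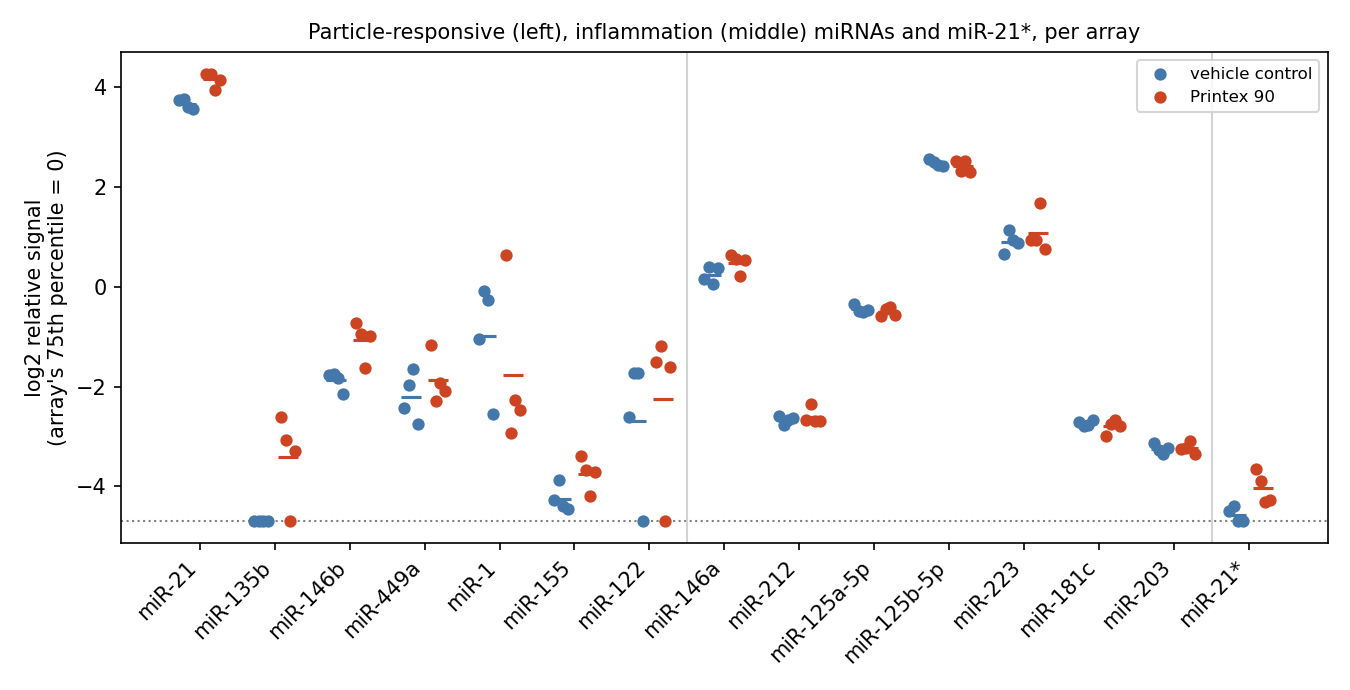
Log2 relative signal on each array for the tested members of the particle-responsive list (left), the remaining tested members of the inflammation list (middle) and miR-21* (right). Points are arrays, bars are group means, and the dotted line is the floor. The 4 Printex 90 arrays lie above the 4 controls for miR-21, miR-146b and miR-21*, and 3 of them for miR-135b. miR-21* was detected on 1 control array, and miR-1 and miR-122 spread widely within both groups.

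Marker miRNAs of white blood cells gave no call as a group. Of 10 tested members of the leukocyte list, 3 were higher and 7 lower (median -0.03, camera adjusted p = 0.741), and the 3 higher were miR-155, miR-146a and miR-223, which the inflammation list also holds. miR-142-3p (-0.02), miR-142-5p (-0.06), miR-150 of lymphocytes (-0.14) and miR-342-3p (-0.02) did not differ beyond the spread, and miR-181b (-0.10) had an unadjusted limma p of 0.0399. The red blood cell miRNAs miR-144 and miR-486 measured 2.01 ± 0.27 and 0.254 ± 0.0233 after Printex 90 against 2.52 ± 0.914 and 0.314 ± 0.112 in controls. The erythroid list (5 tested, 0 higher and 4 lower) had a median of -0.20 and was not called (camera adjusted p = 0.752). Its median was -0.03 without vehicle control replicate 1, which had the highest miR-144 and miR-486, and -0.04 without Printex 90 replicate 3.

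Epithelial miRNAs were higher by a small amount: 8 of 11 tested members were higher and 2 lower, with a median of 0.04. Their call in camera (adjusted p = 0.00692) was lost with an estimated correlation (adjusted p = 0.665 with an estimated correlation) and without Printex 90 replicate 3 (adjusted p = 0.0992). Without scaling between arrays the median was -0.01. miR-31 measured 0.189 ± 0.0145 against 0.164 ± 0.00968 (log2 difference 0.20, limma adjusted p = 0.706) and miR-141 of the miR-200 family 1.57 ± 0.108 against 1.47 ± 0.0844. Of the 5 tested miRNAs of multiciliated airway cells, 4 were higher (median 0.14, camera adjusted p = 0.181), among them miR-34b-5p (0.15, SE 0.19). That list was called without vehicle control replicate 3 (adjusted p = 0.0188), without Printex 90 replicate 2 (adjusted p = 0.0484) and with no filter (adjusted p = 0.0452). Each call was lost with an estimated correlation (adjusted p = 0.761, 0.859 and 0.435 with an estimated correlation).

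Lists of resident structural cells and regulatory families gave no call. The medians were -0.08 for 9 endothelial miRNAs (camera adjusted p = 0.296), with miR-126-5p at -0.20 and miR-27b at -0.06, and -0.03 for 10 miRNAs of smooth muscle and mesenchymal cells (camera adjusted p = 0.914), with miR-199b* at -0.09 and miR-214* at -0.18. The fibrosis list of 15 tested miRNAs had a median of -0.04 (camera adjusted p = 0.914). Its 1 member past the threshold over the list alone was miR-21 (limma adjusted p = 0.0113), while miR-29a, miR-29b and miR-29c, which repress collagen genes, lay between -0.03 and 0.02, and miR-30e at -0.07. The let-7 family (9 tested) had a median of -0.04, with let-7b at -0.05, and the miR-17-92 cluster and its paralogs (11 tested) -0.04, with miR-25 at -0.11 and miR-18a at 0.08 (camera adjusted p = 0.914 each). The hypoxia and oxidative stress list (10 tested) had a median of -0.05, with miR-181a at -0.10 (camera adjusted p = 0.914). Of 59 Dlk1-Dio3 cluster miRNAs 12 were tested (median 0.01, camera adjusted p = 0.598), with miR-411* at 0.16 and miR-485* at -0.19. Only 3 of 9 neural miRNAs were tested (median 0.05, camera adjusted p = 0.0936), among them miR-128 (0.03) and miR-129-3p (0.08), and that list was called without Printex 90 replicate 1 (adjusted p = 0.0119) and with array weights (adjusted p = 0.00718). Both calls were lost with an estimated correlation (adjusted p = 0.545 and 0.340 with an estimated correlation). The medians of the leukocyte, smooth muscle, fibrosis, let-7, miR-17-92 and hypoxia lists changed sign when the 75th percentile was taken over all mouse miRNAs, and those of the leukocyte, fibrosis and miR-17-92 lists also with quantile normalization. The epithelial, neural and Dlk1-Dio3 medians changed sign without scaling. The leukocyte list had a negative median but a mean of 0.04 and an upward camera direction, the fibrosis list a negative median and mean but an upward camera direction, and the Dlk1-Dio3 list a positive median but a mean of -0.02.

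**Figure D3:**
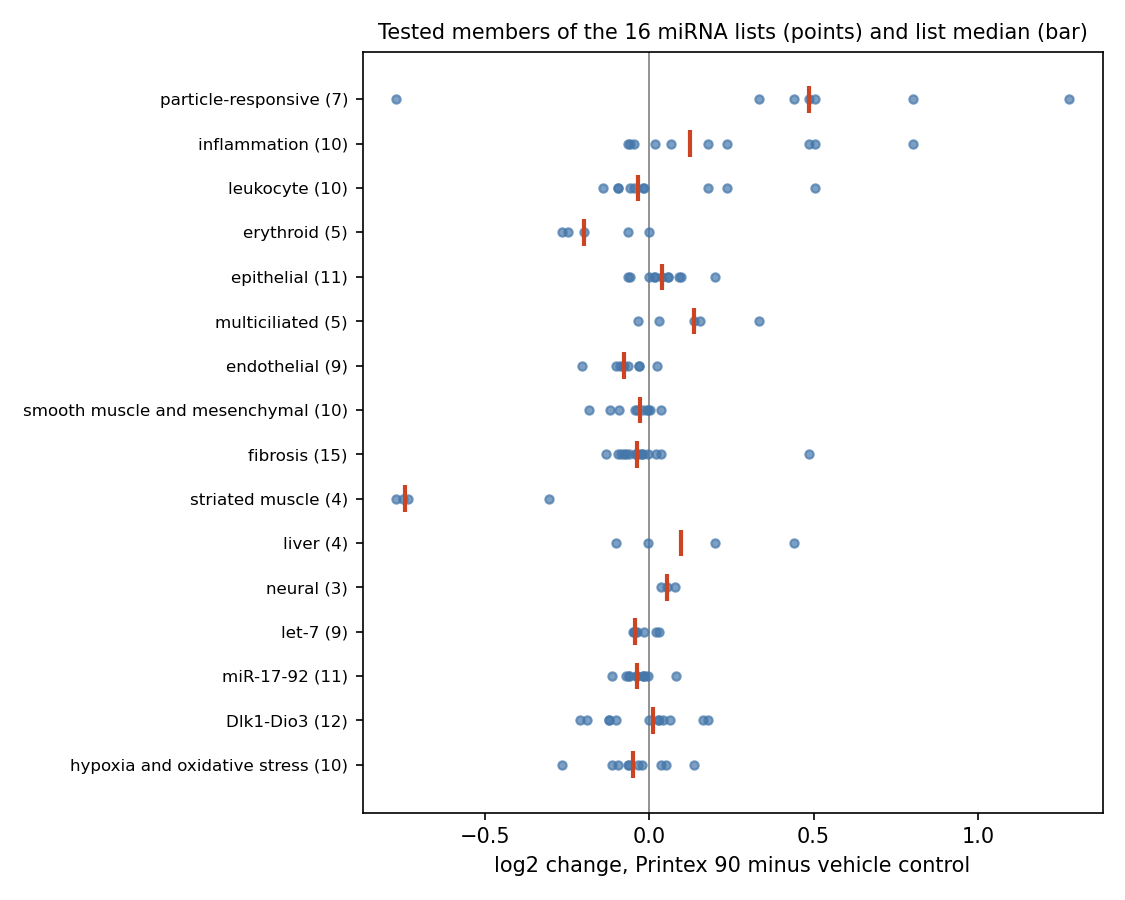
Log2 difference (Printex 90 minus vehicle control) of each tested member of the 16 lists (points, number of members in brackets) and the median of each list (bar). The particle-responsive median lies at 0.49 and the striated muscle median at -0.74, and the other medians lie between -0.20 and 0.14.

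The striated muscle miRNAs miR-1, miR-133a and miR-133b differed many-fold from array to array within both groups. miR-1 ranged over the 8 arrays by 11.9-fold, and miR-133a, which varied least of the 3, by 10.9-fold, where the median of 237 other miRNAs detected on all arrays was 1.31-fold. All 4 tested members were lower after Printex 90 (median log2 difference -0.74, camera adjusted p = 0.391), and the list's mean log2 signal did not differ beyond the spread (exact permutation p = 0.457, 2-sided). Without Printex 90 replicate 1, the array with the highest miR-1, the median was -1.52 (camera adjusted p = 0.00584, and adjusted p = 0.545 with an estimated correlation). miR-206 of skeletal muscle measured 0.0447 ± 0.00876 against 0.0568 ± 0.00754 (log2 difference -0.30, limma adjusted p = 0.706). Of the liver list 4 miRNAs were tested (median 0.10, camera adjusted p = 0.329), with miR-194 at -0.10. miR-122 was under the floor on vehicle control replicate 4 and Printex 90 replicate 3 and lay between 0.164 and 0.439 on the others.

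**Figure D4:**
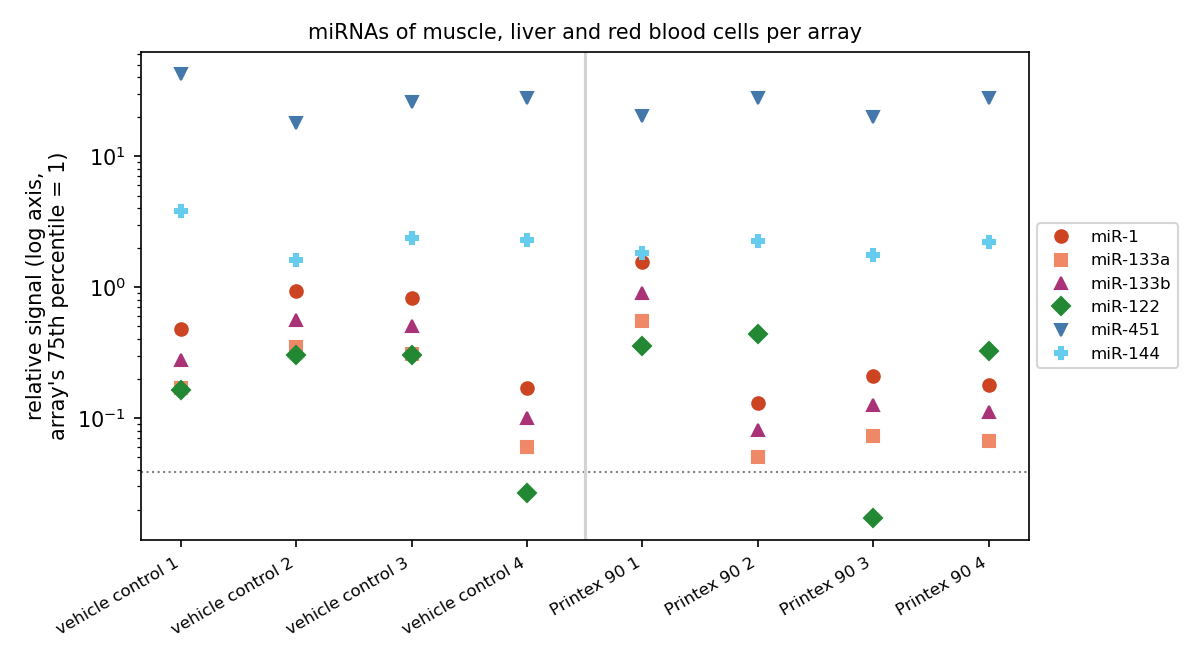
Relative signal (log axis, array's 75th percentile set to 1) of miR-1, miR-133a and miR-133b of striated muscle, miR-122 of liver, and miR-451 and miR-144 of red blood cells on each of the 8 arrays, with the floor dotted. The 3 muscle miRNAs move in parallel, from a miR-1 of 0.131 on Printex 90 replicate 2 to 1.55 on Printex 90 replicate 1.

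The 5 miRNAs with the brightest signals did not differ beyond the spread. miR-720, an array name since assigned to a transfer RNA fragment, measured 42.5 ± 4.94 after Printex 90 and 41.6 ± 1.78 in controls, and the endothelial miR-126-3p 37.9 ± 3.53 and 40.6 ± 2.62. The erythroid miR-451 measured 28.5 ± 10.3 in controls, with a log2 difference of -0.20 (SE 0.27). let-7f measured 17.8 ± 1.25 and 18.3 ± 0.511, and let-7a 16.7 ± 1.19 and 17.2 ± 0.436. The number of detected mouse miRNAs was 261.0 ± 15.2 after Printex 90 and 266.8 ± 14.4 in controls (exact permutation p = 0.629, 2-sided). The log2 75th percentile of the signal before scaling was 9.35 ± 0.14 and 9.42 ± 0.16 (exact permutation p = 0.571, 2-sided). Of the 39 herpesvirus miRNAs, used as a background that mouse lung should lack, 3 were detected on each of 7 arrays and 4 on Printex 90 replicate 2. The brightest, mghv-miR-M1-2, measured 0.241 ± 0.0304 and 0.241 ± 0.0258 relative to the 75th percentile. The group means of miR-135b, miR-155 and miR-21* lay below this signal, where detection alone does not show that a signal is specific.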

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

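All tests of explanations in this part were chosen after the results were seen. The gap between the extreme array and the nearest other, divided by the range of its group, was compared with Dixon's 95% limit in 98 groups of 4 arrays. It was exceeded in 6, where chance, which exceeds it in about 1 of 20 groups, gives 4.9. miR-122 on Printex 90 replicate 3 lay far below its group (log2 relative signal at the floor of -4.69, next lowest -1.61, gap 0.880 of the range). miR-212 on Printex 90 replicate 2 was high (-2.35, next -2.68, gap 0.954), as was miR-199b* on Printex 90 replicate 3 (1.30, next 1.11, gap 0.979). let-7b and miR-126-3p on vehicle control replicate 2 were low (3.45, gap 0.922, and 5.20, next 5.38, gap 0.893). miR-25 on vehicle control replicate 1 was high (-0.23, next -0.51, gap 0.851).

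Of the 7 particle-responsive miRNAs 6 were higher after Printex 90, with a median log2 difference of 0.49, and miR-1 was lower, but the list was not called with an estimated correlation (adjusted p = 0.335 with an estimated correlation). With the preset correlation 1 of the 35 splits of the 8 arrays, the real one, reached a -log10 camera p of 6.96 (highest other 6.81). A median as large was reached by 3 of 35 (real 0.49, highest other 0.66). Chance is not excluded for either measure. For camera, 1 of 35 is the smallest share possible, and the preset correlation of 0.01 lies far below the estimated 0.642. More leukocytes of all kinds already in the lungs would be expected to raise their marker miRNAs. The 7 markers outside both responsive lists were miR-142-3p, miR-142-5p, miR-150, miR-342-3p, miR-181a, miR-181b and miR-181d. Their mean differed by -0.07, with an upper 95% bound of 0.0305. The tested members left out, miR-155, miR-146a and miR-223, were the 3 higher ones of the leukocyte list, so this mean cannot decide the question. More neutrophils and macrophages alone were neither seen nor excluded: their miR-223, which the inflammation list holds, differed by 0.18 with an upper bound of 0.68, but by 0.05 without Printex 90 replicate 3. That array had the highest miR-223 of all (3.21) and the lowest miR-21, miR-146b, miR-155 and miR-135b of its group (15.5, 0.323, 0.0547 and 0.0382). It also had the lowest 75th percentile signal (580.8) and the fewest detected mouse miRNAs (248) of all arrays, and 1 array cannot decide this. The row of the slide, of which 0 hold arrays of both groups, cannot be told apart from the exposure, so the pattern may also reflect array position.

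miR-1, miR-133a and miR-133b varied by 10.9-fold to 11.9-fold over the arrays. The 95th percentile of the ranges of other miRNAs was 1.90-fold. All these signals had been divided by each array's 75th percentile, which removes a difference in signal level, so the ranges cannot test it. Before scaling, that percentile ran from 580.8 to 804.7 intensity units, a far smaller spread than that of the muscle miRNAs. Differing amounts of striated muscle in the lung pieces stay open: the ratios of miR-1 and of miR-133b to miR-133a varied by at most 1.10-fold, but miR-1 and miR-133a share primary transcripts, and miR-133a and miR-133b are near-identical sequences that probes may not tell apart. miR-206, from the miR-133b locus, did not follow (0.0526 on Printex 90 replicate 1, 0.0507 on replicate 2), though it lay near the floor, and of the 8 list members on the array the heart miRNAs miR-208a, miR-208b and miR-499 were not detected. An effect of Printex 90 on these miRNAs was neither seen nor excluded (exact permutation p = 0.457).

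The inflammation list reached a -log10 camera p of 4.42 in 1 of 35 splits, the real one, with 3.55 as the highest other. In the main setting the list was called at the preset correlation only (camera adjusted p = 0.107 with an estimated correlation). Its median was reached in 2 of 35 splits (real 0.1227, highest other 0.1232). Chance is not excluded for either measure, as 1 of 35 is the smallest share that the splits can give. The epithelial list was matched or exceeded in 5 of 35 splits (real 2.89, highest other 4.75), so chance is not excluded. The real split gave 0 miRNAs past an adjusted p of 0.05, which all 35 splits must match or exceed, so that comparison decides nothing. The highest count, 26, came from vehicle control replicates 1 and 4 with Printex 90 replicates 3 and 4 against the rest. It was picked out after all splits were seen, and its cause was not tested. The 15 miRNAs at an unadjusted p under 0.05 were matched or exceeded in 13 of 35 splits, with 75 as the highest.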

How the results depend on the processing

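Normexp on the median spot signal, the uncorrected median signal level, leaving out miRNAs at the floor, leaving out both arrays low in miR-122, the shortened lists and the other viral detection rules were chosen after seeing the data. Normexp and the uncorrected signal level had been planned on the mean spot signal, which the files lack, so the median spot signal was used. limma called 0 miRNAs in all settings except the mean of the probes' log2 values (1, miR-135b), both arrays low in miR-122 left out (2, miR-21 and miR-146b) and single arrays left out (0 to 2); the cause was not tested. At an adjusted p of 0.1 the main setting also gave 0, but the lowest adjusted p was under 0.1 in 6 further settings (0.0588 to 0.0932). The unadjusted count of 15 (8 higher, 7 lower) ran from 7 (6, 1) without Printex 90 replicate 4 to 32 (6, 26) with the mean of probes, and lower miRNAs were 0 with normexp, the brightest probe and without Printex 90 replicate 3. miR-21 and miR-146b were higher in all 27 alternatives (log2 0.42 to 0.63 and 0.58 to 1.06, adjusted p 0.0198 to 0.827 and 0.0190 to 0.896). Dim miRNAs, limited by background, kept their sign but moved more: miR-135b ran from 0.37 (normexp) to 2.47 in 21 alternatives, and miR-155 and miR-21* went down to 0.07 and 0.01 with the floor doubled, which covers most of their signals. At the preset correlation, the particle-responsive list kept its call except without the miRNAs shared with the inflammation list (median 0.39, adjusted p = 0.0971), and with an estimated correlation it was called in no setting (adjusted p 0.0701 to 0.798). Over single arrays left out its median ran from 0.29 without Printex 90 replicate 1 to 0.68 without Printex 90 replicate 3. Members past the threshold over that list alone ranged from 1 to 3 with single arrays left out. At the preset correlation the inflammation list lost its call without the miRNAs shared with the particle-responsive list (median 0.0168, adjusted p = 0.374). The epithelial call ended without scaling (median -0.0150, adjusted p = 0.088), with the mean of probes (median -0.00694, adjusted p = 0.0538), with array weights (median 0.00355, adjusted p = 0.0731), with both arrays low in miR-122 left out (median 0.0296, adjusted p = 0.234) and without Printex 90 replicate 3 (adjusted p = 0.0992, medians of 0.0212 to 0.0794 over single arrays left out); the cause was not tested. The number of lists called was 3, and 2 to 5 with single arrays left out, the 5 without Printex 90 replicate 1. With an estimated correlation 0 lists were called, and 1 (inflammation) with miRNAs detected on all 8 arrays and with no filter. Detected viral miRNA probes averaged 3.125, against 2.75 with every spot well above background and 3.875 by the software's flag. The differences in detected miRNAs (-5.75) and in array signal level before scaling (-0.07) passed no threshold in any setting; without vehicle control replicate 4 the latter was 0.00552. Same-numbered arrays correlated at -0.13, -0.38, -0.47 and 0.44 in their deviations from the group means, so the miRNA values gave no pairing by number. The number equals the slide column in both groups, and local background followed it (20.8 and 20.7 in column 1, 18.2 and 18.4 in column 4), so a block on it covers the column. With that block limma called 0 miRNAs and camera 3 lists. Of 1224 recomputed values of named miRNAs, 45 changed sign without a call, as did 44 of 434 list medians.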

Other observations

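The test in this part was chosen after the pattern was seen. The miRNAs of the miR-297, miR-466, miR-467 and miR-669 families, which come largely from a repetitive cluster in an intron of Sfmbt2, were lower after Printex 90 in 25 of 26 tested members, with a median log2 difference of -0.14. That median lay at the 0.01 percentile of 10000 random lists of matched brightness. The median was also below 0 with the percentile over all mouse miRNAs (-0.09), quantile normalization (-0.09) and no scaling (-0.21). A hypothesis that exposure lowers the family did not stand out from other arrangements of the arrays: 11 of the 35 splits gave a median as large (real 0.14, highest other 0.27), so chance may give the pattern. The exact permutation p of the mean was 0.286. Random lists treat miRNAs as independent, and these related sequences move together between arrays.

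The red blood cell miRNAs miR-451, miR-144 and miR-486 moved together between arrays and were highest on vehicle control replicate 1 (42.6, 3.79 and 0.474). Their ranges over the 8 arrays were 2.38-fold, 2.35-fold and 2.21-fold. The first principal component held 54.3% of the variation among tested miRNAs, of which miR-1, miR-133a, miR-133b and miR-122 made up 67.5%, and 37.1% once the striated muscle list and miR-122 were left out. Correlations between arrays over the tested miRNAs were 0.981 to 0.998 within groups and 0.977 to 0.996 between them.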
